A study of Rattus norvegicus with 11 samples.

How the data were processed

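Liver RNA of 11 rats (6 Control, 5 TPN) was extracted with TRIzol and sequenced as small RNA libraries on an Illumina HiSeq 4000, per the labels' protocols. The authors deposited 1 table with 1 column per rat and 1 row per microRNA, in CPM: the values of each deposited column sum to 1000000 over the rows of the table. DESeq2 is named, without a version or a role, per the submitters' processing notes. The trimming, aligner, counting, microRNA database, genome build and filters are not given in the sources used here. How reads of nearly identical microRNAs were divided is not given either, and 28 of the tested rows fell into 13 sets with identical values in all libraries, which are reported as deposited.

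Each non-zero value was a whole multiple of the smallest value of its column, so reads were recovered by division; 100% of the non-zero values came out whole within a tolerance of 0.001. The recovered totals count only reads assigned to rows of the table, and reads lost before that step are not seen. A count of 0 allows up to 3 reads of the total, which is 0.203 CPM in TPN 8 and 2.14 CPM in Control 12. The exact Clopper-Pearson 95% interval of a library's share spans at most 0.165 percentage points for miR-148a-3p, 0.0964 for the 10 most abundant, 0.110 for miR-122-5p and 0.0463 for predicted rows. Such intervals and limits cover counting error only, since no molecular identifiers are stated.

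The planned design assumed counts and edgeR. Because the deposited unit was CPM, the test planned for normalized values was used: limma-trend on log2(CPM + 1) over rows with a mean of at least 1 CPM, with no further scaling, all 11 rats, no covariate and Benjamini-Hochberg adjustment (R 4.3.3, limma 3.58.1). Fold changes are given with the moderated standard error. On the recovered reads, edgeR 4.0.16 (quasi-likelihood, TMM), DESeq2 1.42.0 and limma-voom were run as alternatives; they called 0, 112 and 0 rows at an adjusted p under 0.05. Shares and totals were compared with 2-sided exact permutation tests over all 462 regroupings. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry; smaller lists are described by counts. A row belonged to a list by its microRNA number and letter, either arm. Figures were drawn with matplotlib 3.10.9.

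The planned rule named the 5 rows with the smallest p in each direction with a mean of at least 10 CPM (because fewer than 5 passed), the 5 most abundant, miR-431, miR-122, miR-34a, miR-21, miR-192 and miR-210, and of each described list its most abundant member with up to 3 members of smallest p. After the results were seen, this was reduced from 4 members to the 2 with the smallest p and the most abundant (all members where at most 3 were measured), which took the named set from 44 to 35, and the 10 lists described by members were picked at that time. Other names were chosen after their values were seen, and the text says so.

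No pair of libraries agreed within sampling noise: the closest, Control 16 and Control 18, had a chi-square of 160 per degree of freedom. The labels name no batch. Rat numbers below 10 and of 10 or more were compared as a possible batch, and Control 5, 12 and 19 were left out together, both after seeing the data. Exploratory fits with other scalings and tests had been looked at before the final ones were written. The fits were tested on 10 simulated data sets with the real means, dispersions and totals of the 535 rows and 200 changed rows each. For the TPN against Control design, limma-trend recovered 7.5% of rows changed by a factor of 2 and 35% of those changed by a factor of 4, and 1.84% of its calls were false; in 10 unchanged data sets it made 0 calls. Each simulated row was drawn independently around the same base mean in all libraries, with dispersions estimated without the group. The simulations thus lack rows that vary together and the excess of predicted reads in Control 5, 12 and 19. Their rates of recovered and false calls may therefore not hold for the real libraries. Other scalings, filters, pseudocounts, row sets and leaving out each library were tried. The reference gene table (assembly GRCr8) was used only to see which microRNA genes neighbour each other, and no coordinates are given because the deposited table states no build.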

Results

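The series profiled small RNA in the liver of male Sprague-Dawley rats, an outbred laboratory strain, that entered the experiment at 4 weeks of age. For 7 days, 5 rats received total parenteral nutrition (TPN), in which all nutrients are infused into a vein and the gut receives no food, and 6 Control rats received chow with intravenous 0.9% saline. The title of the series places the comparison in the study of liver injury in intestinal failure and of ferroptosis, an iron-dependent cell death that the lipid peroxide-reducing enzyme GPX4 restrains. Each sample was named as a numbered rat and is called here by its group and that number. The table held 1331 rows. Of these, 533 carried names of known rat microRNAs and 798 carried names of predicted microRNAs (novel_miR_ and a number). Values were counts per 1000000 reads (CPM). The reads behind them could be recovered as whole numbers and came to between 1404858 (Control 12) and 14788757 (TPN 8) per library. The mean was 5662809 ± 3414685 (SD, n = 6) in Control and 9571058 ± 2947310 (SD, n = 5) in TPN, a difference that did not pass a 2-sided exact permutation test (p = 0.0866).

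The 10 most abundant microRNAs together took a larger part of the liver library in TPN than in Control. Their joint share was 93.1% ± 0.471 (SD, n = 5) in TPN and 91.5% ± 0.651 (SD, n = 6) in Control, and every TPN rat (92.6% to 93.8%) lay above every Control rat (90.6% to 92.2%). The exact permutation p was 0.00216, the smallest that the 462 regroupings of the rats can give, and 0.00649 after Benjamini-Hochberg adjustment over the 3 planned library measures. All the other rows together held 8.51% ± 0.651 of the reads in Control and 6.90% ± 0.471 in TPN. Of the 10, only miR-148a-3p had a higher mean share in TPN, and each of the others had a lower one. None of these single differences passed an exact permutation test (smallest p = 0.0931). The difference in the top-10 share was 1.77 percentage points among rats numbered below 10 and 1.54 among rats numbered 10 or more, and 1.28 without Control 5, 12 and 19 (exact permutation p = 0.0179). As the groups did not overlap with all rats, the direction in these subsets and that p were fixed in advance, and only the sizes were free.

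Among these 10, miR-148a-3p, a microRNA abundant in hepatocytes, held the largest share in each library. It averaged 56.3% ± 7.45 (SD, n = 5) of the reads in TPN and 47.8% ± 9.02 (SD, n = 6) in Control (exact permutation p = 0.128). Without Control 5, 12 and 19 its difference was 16.4 percentage points (exact permutation p = 0.0357). The liver-specific miR-122-5p averaged 13.7% ± 9.30 in TPN and 15.7% ± 14.2 in Control (exact permutation p = 0.792) and ranged from 2.18% in Control 19 to 33.5% in Control 18. The next were miR-21-5p (8.23% ± 1.03 in TPN and 9.05% ± 6.13 in Control), miR-192-5p (5.61% ± 1.19 and 6.18% ± 1.62) and miR-101b-3p (3.02% ± 2.23 and 4.78% ± 4.38), and none of these differences was larger than the spread between rats (exact permutation p of 0.961, 0.526 and 0.522).

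**Figure D1:**
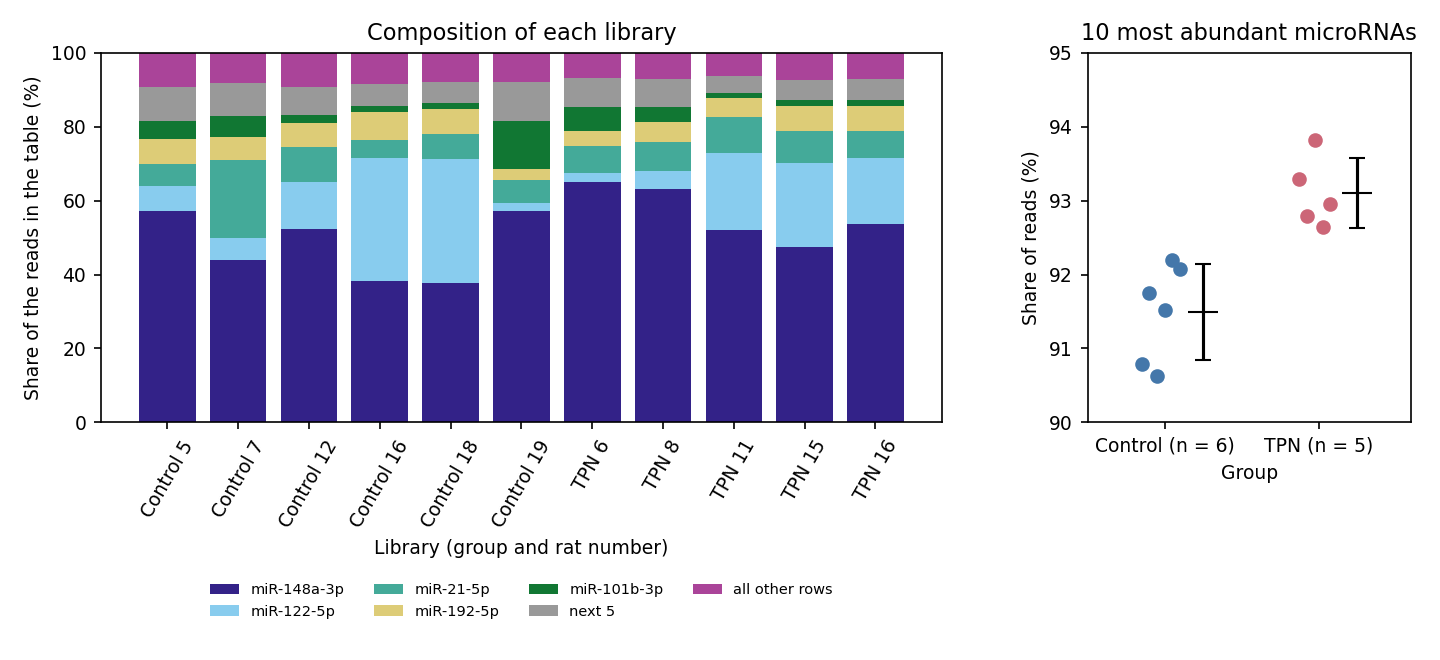
Left, the share of each library's reads (%, y axis) taken by the 5 most abundant microRNAs, the next 5 and all other rows, for each of the 11 rats (x axis). Right, the joint share of the 10 most abundant microRNAs per rat on a y axis from 90% to 95%, with bars for the mean and 1 SD; the TPN rats lie between 92.6% and 93.8% and the Control rats between 90.6% and 92.2%.

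The predicted rows set 3 Control libraries apart. In Control 5, 12 and 19, the 3 with the fewest reads, predicted rows held 0.517%, 2.0% and 0.560% of the reads, against 0.0965% to 0.145% in the other 8 libraries. Reads were found in 618, 625 and 490 predicted rows of these 3 libraries and in 230 to 325 of the others. The group difference in the predicted share was 0.119% ± 0.0182 (SD, n = 5) in TPN against 0.576% ± 0.725 (SD, n = 6) in Control, with an exact permutation p of 0.0931.

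**Figure D2:**
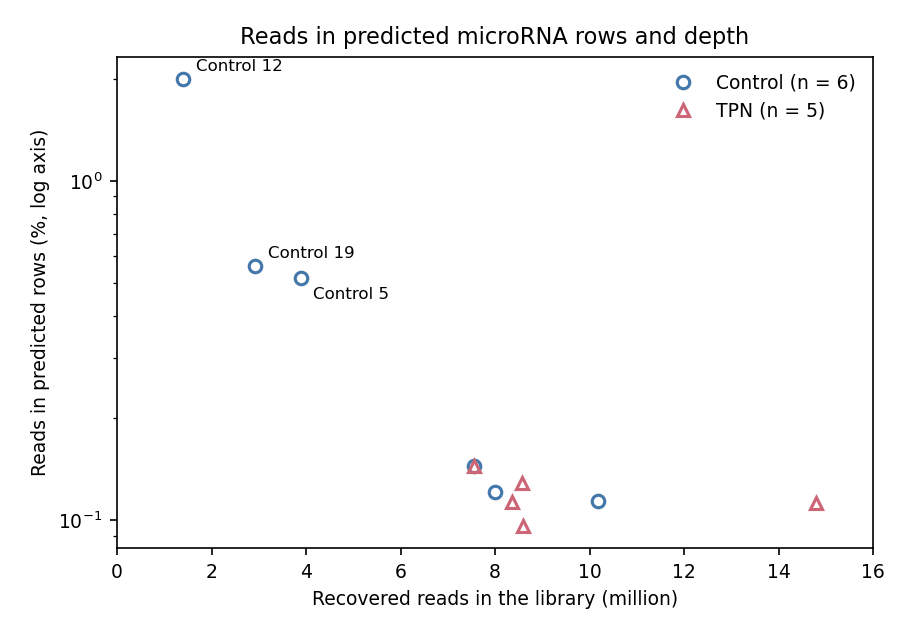
Share of reads in predicted microRNA rows (%, logarithmic y axis) against the recovered reads of each library in units of 1000000 (x axis), 1 point per rat, with Control as circles and TPN as triangles. Control 5, 12 and 19 lie at 0.517%, 2.0% and 0.560%, and the other 8 libraries lie between 0.0965% and 0.145%.

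The comparison of TPN with Control asked which microRNAs differed in level. Of 535 rows with a mean of at least 1 CPM (280 rat-named, 255 predicted), none was higher and none was lower in TPN at an adjusted p under 0.05 (limma-trend, Benjamini-Hochberg); the smallest adjusted p was 0.296. At an unadjusted p under 0.05, 1 row was higher and 60 were lower, where 26.75 in all would be expected by chance, and 31 of the 60 were predicted rows. The 60 became 25, 130, 147, 153 and 38 without Control 5, 7, 16, 18 and 19, 21, 29 and 22 without TPN 11, 15 and 16, and 36 without Control 5, 12 and 19 together. The counts were 6 higher and 27 lower with RLE, 7 and 27 with TMM, 33 and 56 with upper-quartile scaling, 7 and 6 with limma-voom, 7 and 168 with edgeR and 10 and 232 with DESeq2. With the recovered reads, edgeR and limma-voom called 0 higher and 0 lower, and DESeq2 called 3 higher and 109 lower, 105 of them predicted rows and all 109 highest in Control 5, 12 or 19. The median log2 fold change of the rat-named rows was -0.26 on the deposited scale, 0.10 after TMM scaling and 0.91 after upper-quartile scaling, so a log2 value near -0.26 below is no change relative to the middle of the table. A positive value under 0.91 with upper-quartile scaling is still below that middle. Fold changes are on the log2(CPM + 1) scale, which understates those of rare microRNAs, unless DESeq2, edgeR, limma-voom or a ratio of CPM is named.

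The microRNAs of red blood cells were the group with the largest difference. miR-451-5p and both arms of miR-144, which come from 1 gene cluster and are made in developing red cells, were all lower in TPN, and 3 of 3 passed when adjusted over the list alone (0 of 3 over all rows). miR-451-5p averaged 85.5 CPM ± 95.2 (SD, n = 5) in TPN and 374 CPM ± 265 (SD, n = 6) in Control, a log2 fold change of -2.35 ± 0.63 (SE) with an adjusted p of 0.00763 over the list alone. All 5 TPN rats lay below the Control median. TPN 6 had 250 CPM, above Control 12, 16 and 18, and without it the TPN mean was 44.3 CPM ± 27.3 (SD, n = 4). miR-144-3p had a log2 fold change of -1.21 ± 0.42 (2.57 CPM against 6.58, with 4 of 5 TPN rats below the Control median, and 1.46 CPM without TPN 6) and miR-144-5p of -0.87 ± 0.32 (1.62 CPM against 3.70), each with an adjusted p of 0.0186 over the list alone. The mean of the 3, set against the median rat-named microRNA of the same library, was lower in TPN by a log2 difference of -1.06 (exact permutation p = 0.0238). With TMM scaling 1 of the 3 passed over the list alone, with upper-quartile scaling or edgeR none did, and miR-144-5p turned to 0.018 with upper-quartile scaling, still under its median of 0.91. The log2 fold change of miR-451-5p was -1.95 among rats numbered below 10 and -2.78 among the others, and -1.89 without Control 5, 12 and 19.

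The miR-183, miR-96 and miR-182 cluster, 3 related microRNAs transcribed together, was also lower in TPN, with 2 of 3 past the threshold when adjusted over the list alone and 0 of 3 over all rows. miR-96-5p, the row with the smallest p of the table, averaged 11.4 CPM ± 3.02 in TPN and 26.5 CPM ± 7.49 in Control, a log2 fold change of -1.14 ± 0.29 with an adjusted p of 0.00464 over the list alone. All 5 TPN rats lay below every Control rat, but by less than 1 read. TPN 15 had 14.1 CPM and Control 12 had 14.2 CPM, where 1 read is 0.712 CPM. miR-183-5p had a log2 fold change of -0.94 ± 0.39 and miR-182 of -0.98 ± 0.51. Among the 11 rats, with group means removed, miR-182, miR-183-5p and miR-96-5p had correlations of 0.803, 0.740 and 0.459 with the red cell marker miR-451-5p. These single values were not tested against other rows. The list of 8 red cell rows that holds them had a median of 0.541, at the 85.65th percentile of random lists, which left that test open. The cluster is thus not shown to have changed apart from miR-451-5p, nor to follow it. With TMM scaling or edgeR none of the 3 passed over the list alone, and with upper-quartile scaling all 3 values were positive but under its median of 0.91 (0.12, 0.43 and 0.41). Only 1 member passed without Control 5, 12 and 19 together, and also without Control 5, 7, 18 or 19 or TPN 11, 15 or 16 alone.

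Other rows with the smallest p among those lower in TPN also missed the threshold. miR-505-3p had a log2 fold change of -0.996 ± 0.28 (14.1 CPM in TPN, 28.9 in Control), miR-7a-5p of -0.70 ± 0.21 (677 CPM and 1091 CPM) and miR-203a-3p, abundant in stratified epithelia, of -0.83 ± 0.26 (98.4 CPM and 180 CPM), each with an adjusted p of 0.296. Of these, miR-505-3p passed with DESeq2, as did miR-96-5p. With upper-quartile scaling the 3 values were 0.31, 0.70 and 0.55, positive but under its median of 0.91. In the miR-15/16 family, which restrains cell cycle genes, all 8 measured members had negative values and 0 of 8 passed over the list alone or over all rows; miR-15b-5p had a log2 fold change of -0.997 ± 0.32 and miR-16-5p, its most abundant member, of -0.90 ± 0.35, against 0.30 and 0.48 with upper-quartile scaling.

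**Figure D3:**
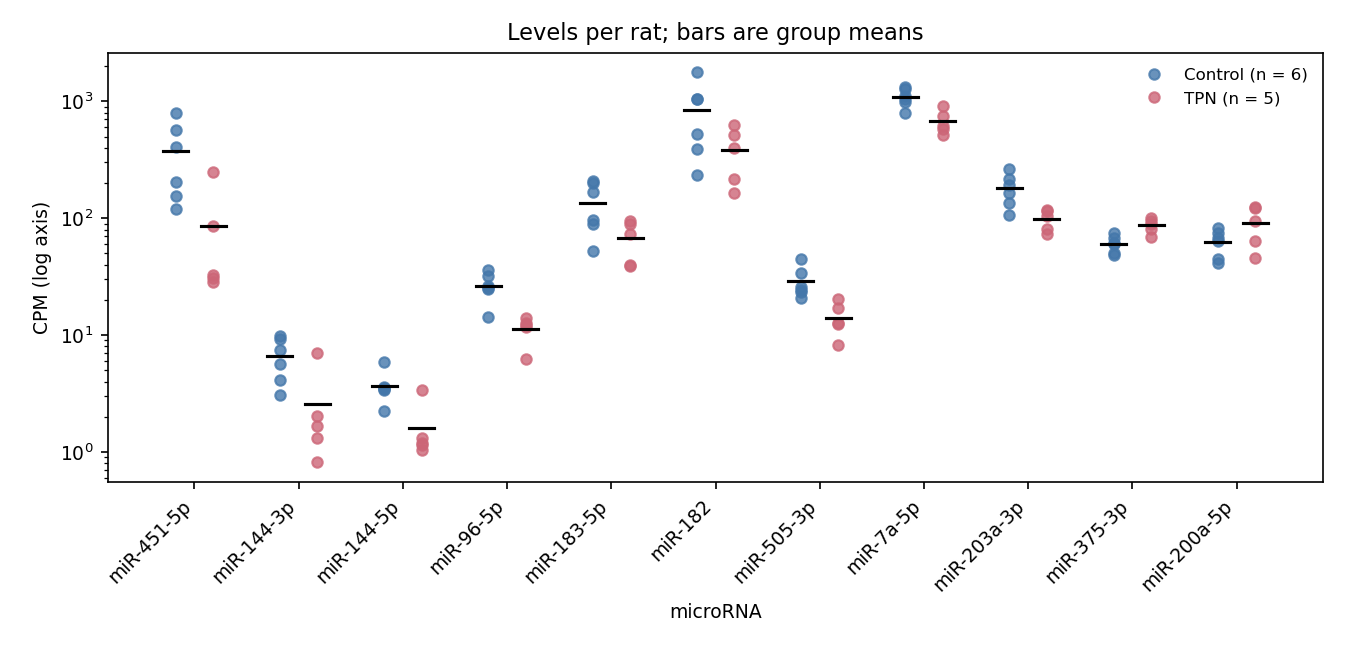
CPM per rat (logarithmic y axis) of 11 named microRNAs (x axis), with Control rats in blue, TPN rats in red and black bars for group means. miR-451-5p averaged 374 CPM in Control and 85.5 CPM in TPN, and miR-375-3p averaged 60.3 CPM in Control and 87.2 CPM in TPN.

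On the higher side, miR-375-3p, known from pancreatic islets and some epithelia, was the row with the smallest p. It averaged 87.2 CPM ± 12.6 (SD, n = 5) in TPN and 60.3 CPM ± 10.2 (SD, n = 6) in Control, and all 5 TPN rats lay above the Control median. Its log2 fold change was 0.53 ± 0.20 with an adjusted p of 0.296 over all rows, and 0.0183 over its list alone, of which it was the only measured member. DESeq2 gave it an adjusted p of 4.04e-05, while no limma or edgeR fit did under 0.05 (the smallest was 0.0808, edgeR with robust dispersion). It stayed positive under every scaling (0.93 with TMM, 1.90 with upper quartile). The other rows with the smallest p on this side were miR-200a-5p (0.47 ± 0.30), miR-200a-3p (0.35 ± 0.31), miR-148a-3p (0.25 ± 0.23) and miR-1843a-5p (0.26 ± 0.25), none of which passed. DESeq2 called miR-148a-3p higher, with a log2 fold change of 0.59 and an adjusted p of 0.0047.

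Of 35 lists fixed before the data were examined, 23 had at least 5 measured members and were tested with camera. It compares a list's members with all other rows, predicted rows included. The miR-200 family with miR-141 and miR-429, a mark of epithelial cells such as those of bile ducts, stood higher than the other rows (adjusted p = 0.00697), with 5 of 7 members positive and a median log2 fold change of 0.19. The miR-148 and miR-152 family did so too (adjusted p = 0.0124), with 5 of 6 members positive and a median of 0.11. With an estimated correlation neither call held (p = 0.0735 and 0.0607, adjusted p = 0.62 for both). No member of either family passed over all rows or when adjusted over the list alone. Among the members of the first family, miR-200b-3p, its most abundant, had a log2 fold change of 0.22 ± 0.38 and miR-200c-3p of -0.83 ± 0.29 (0.41 with upper-quartile scaling). In the second, miR-148b-3p had -0.49 ± 0.29 (0.91 with upper-quartile scaling). Both calls were also lost against rat-named rows only (adjusted p = 0.124 and 0.184) and without Control 5, 12 and 19 (adjusted p = 0.997 and 0.195); without these 3 libraries the let-7 family (adjusted p = 0.00325) and the list of stellate cell, fibroblast and smooth muscle microRNAs (adjusted p = 0.0350) stood lower, while with TMM and RLE scaling the let-7 family stood higher (adjusted p = 0.00535 and 0.0128).

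Lists of the cell types of the liver other than red blood cells showed no call over all rows or adjusted over the list alone. Of all 280 rat-named rows tested, only 58 had positive values, so negative values alone do not set a list apart. Camera placed the hepatocyte, immune and biliary lists on the higher side of the other rows without a call. These other rows include 255 predicted rows, whose median log2 fold change was -1.15. The immune list stood on that side although its median of -0.33 lay below the rat-named median of -0.26. Lists on the higher side went from 19 to 13 of 23 against rat-named rows only. With TMM and RLE scaling camera called the hepatocyte list (adjusted p = 0.0167 and 0.0353) and the biliary list (0.0385 and 0.0484) higher, the latter also without Control 19 (0.0485) or TPN 16 (0.0201). Of 14 measured hepatocyte microRNAs, 11 had negative values (camera toward higher, adjusted p = 0.238); miR-194-5p had a log2 fold change of -0.51 ± 0.20, miR-122-3p of -0.48 ± 0.24, and both turned positive with upper-quartile scaling (0.88 and 0.91). Of 10 blood and immune cell microRNAs, 9 were negative (camera toward higher, adjusted p = 0.817), among them miR-150-5p, a lymphocyte microRNA (-0.56 ± 0.25), miR-342-3p (-0.74 ± 0.39) and miR-146a-5p, which NF-kB induces (-0.48 ± 0.26). Of 7 stellate cell, fibroblast and smooth muscle microRNAs, 7 were negative (camera toward lower, adjusted p = 0.383), with miR-143-5p at -0.62 ± 0.23, miR-214-3p at -0.82 ± 0.35 and the abundant miR-143-3p at -0.43 ± 0.26. Of 11 biliary and epithelial microRNAs, 6 were negative (camera toward higher, adjusted p = 0.172). With upper-quartile scaling the named members of the immune and stellate lists lay between 0.41 and 0.97, around and below its median of 0.91.

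The list of microRNAs with published links to ferroptosis, written from memory and without an assumed direction, had 16 measured members. Of these, 14 were negative, 0 passed over all rows and 0 passed adjusted over the list alone (camera toward lower, adjusted p = 0.900). Its members with the smallest p were miR-7a-5p and miR-144-3p, given above, and its most abundant was miR-26b-5p (-0.71 ± 0.27; 0.69 with upper-quartile scaling). miR-431, an imprinted microRNA on this list, lay under the filter of 1 CPM and did not enter the fit. It had 0 reads in the 33976854 reads of the 6 Control rats, which allows up to 0.0883 CPM, and 16 reads in 4 of the 5 TPN rats, or 0.334 CPM of 47855289 reads (exact Clopper-Pearson 95% interval 0.191 to 0.543). Pooled over the reads of all 5 rats, the TPN level was 3.79 times the limit over the Control group. The lower end of its interval was 2.16 times that limit. This interval covers counting error only, and single TPN rats ran from 0 to 1.06 CPM. TPN 16 gave 8 of the 16 reads. Without it the pooled level was 0.198 CPM, 2.25 times that limit. No interval was taken there, so this is not a smallest fold. The difference in mean CPM went from 0.369 to 0.196 without TPN 16. A 2-sided Fisher's exact test of presence gave p = 0.0152, 1 of 781 rows under the filter that had reads; 3 such rows had reads in at least 4 TPN rats and no Control rat, and 2 had reads in at least 5 Control rats and no TPN rat. A rare row is most easily missed in Control 5, 12 and 19 (0 reads in Control 12 allow 2.14 CPM). Without these libraries the difference in mean CPM stayed at 0.369, with an exact permutation p of 0.196, against 0.0152 with all rats. TPN 15 also had 0 reads, so exchanging it with any remaining Control gives the same difference. With so few rats these ties keep the test from passing, so its p decides nothing. With no filter, limma-trend gave miR-431 an adjusted p of 0.455.

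Of the other microRNAs chosen beforehand, miR-210-3p, which hypoxia induces, averaged 14.8 CPM ± 5.0 (SD, n = 5) in TPN and 25.6 CPM ± 8.78 (SD, n = 6) in Control, a log2 fold change of -0.74 ± 0.33 (adjusted p = 0.296; 0.0458 over its list alone, which held 1 measured row; 0.55 with upper-quartile scaling). The p53-responsive miR-34a-5p had -0.66 ± 0.44 (0.62 with upper-quartile scaling). The injury-associated miR-21-5p had 0.06 ± 0.34, miR-192-5p -0.11 ± 0.27, miR-122-5p -0.03 ± 0.78 and miR-101b-3p -0.49 ± 0.60; all 4 changed sign under at least 1 alternative. On data simulated from these libraries, the limma-trend fit recovered 12.6% of rat-named rows changed by a factor of 2. It recovered 59.2% of those changed by a factor of 4. In such data, changes of the smaller size would mostly go uncalled at this number of rats. The simulated rows were drawn independently of each other, so these rates may not hold for the real libraries. Of the 35 lists, 5 had any member past the threshold over the list alone: those of red blood cells, the miR-183, miR-96 and miR-182 cluster, pancreas, hypoxia, and lipid metabolism (1 of 22, miR-96-5p, adjusted p = 0.0341). These adjustments take each list by itself and do not correct for the 35 lists.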

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

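The tests of the predicted rows and of the red blood cell list, and those of the top-10 share by depth and by predicted rows, were chosen only after those results were seen, as were the counts of splits over all lists and of splits that keep Control 5, 12 and 19 together; the test of the top-10 share without miR-148a-3p and the counts over other splits were fixed before. Some rules changed after a value was seen. The test of a few abundant predicted sequences first asked whether the 5 most abundant predicted rows held under or over 50% of a library's predicted reads; they held 41.2%, 61.3% and 59.9% in Control 5, 12 and 19 and 53.5% to 74.8% in the other 8, which left it undecided, and the test below replaced it. The rule for the 3 shallowest Controls in the red blood cell list was reworded after its p of 0.0893. The result without miR-148a-3p met the bound set beforehand for that microRNA alone as the cause, but is called open because of its spread. Rows seen only in TPN first needed 3 reads, which gave 10 rows; the stricter rule used below dropped miR-107-5p, miR-291a-5p and miR-673-3p.

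The joint share of the 10 most abundant microRNAs was higher in every TPN rat than in every Control rat. Reads in predicted rows account for a part of it but not the whole. With all rats the difference was 1.61 percentage points over all rows and 1.19 among rat-named reads (exact permutation p = 0.00433). Among rat-named reads and without Control 5, 12 and 19, the share was 93.2% ± 0.474 (n = 5) against 91.9% ± 0.333 (n = 3, exact permutation p = 0.0179, the smallest possible there). In those rats predicted rows held at most 0.145% of the reads, so removing them could change little. Among the 7 libraries of 7549952 to 10189899 reads the difference was 1.36 percentage points (4 TPN against 3 Control, exact permutation p = 0.0286). Because the groups did not overlap with all rats, they could not overlap in this subset, so that p decides nothing about depth. Only the size of the difference was free to change there. It remained at like depth, while depth as a part of the full difference stays open. Of the 10, only miR-148a-3p had a higher mean share in TPN, but whether it alone takes the added share stays open. After removing its reads the other 9 held 83.8% ± 3.02 of the rest in TPN and 83.2% ± 3.61 in Control (exact permutation p = 0.773). The difference of 0.609 percentage points on this base is small beside the spread between rats, so a part taken by the other 9 could be missed. RNA handling was not tested.

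The red blood cell microRNAs were lower in TPN, with a mean log2 level of 2.94 ± 0.85 (n = 5) against 4.42 ± 0.49 (n = 6; exact permutation p = 0.0152). A fall of the whole middle of the table is argued against by the difference that remained against each library's median (exact permutation p = 0.0238), although TMM scaling left 1 member past the threshold. Without the 3 shallowest Controls the difference was -1.30, close to the full -1.48, with an exact permutation p of 0.0893, so their part stays open. Less blood of every kind in the TPN samples may be the source and cannot be told apart from a change in red cell precursors: the blood and immune cell list was lower by a log2 difference of -0.33 (exact permutation p = 0.0758), and resident immune cells of the liver could hide a change in blood.

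Control 12 stood apart with 2.0% of its reads in predicted rows, against 0.114% to 0.560% in the other Controls, and Control 5 and 19 came next. Lower depth is argued against: thinned to the depth of Control 12, the other 8 libraries would show at most 149 predicted rows, fewer than any of the 3. A few abundant sequences are not the whole of it, because without each library's 5 most abundant predicted rows the 3 libraries still held 0.224% or more and the other 8 at most 0.0526%. A difference between Control and TPN stays open: TPN differed from the other 3 Controls by -0.00767 percentage points, but Control 5, 12 and 19 were set apart by these same shares, so this value decides nothing. RNA quality and library batch were not tested, as the labels give neither.

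For the red blood cell list, 2 of 100 splits of the rats, the real one included, gave 3 members past the threshold over the list alone (highest of the other splits 3), and 3 of 100 gave as many lists (1; highest other 1) of at least 3 measured members in which all members passed. Among all 56 splits that keep Control 5, 12 and 19 in 1 group of 6, as the real one does, the counts were 4 and 5, above the bound of 5%, so chance could not be excluded. For the 0 rows higher and 0 rows lower at an adjusted p under 0.05 a count of splits decides nothing, since all 100 of 100 must give at least as many. Other splits called up to 30 higher and up to 55 lower. In each of these splits Control 5, 12 and 19 lay together in the same group. Whether a structure among the samples lies behind such calls was not tested. The 60 rows lower at an unadjusted p under 0.05 were matched or exceeded in 7 of 100 splits, real one included (highest other 140), and in 17 of the 56 that keep Control 5, 12 and 19 together, so chance could not be excluded and these 3 libraries have a part in the count. The 2 lists called by camera were matched or exceeded in 84 of 100 splits (highest other 16), which points to rows that vary together from rat to rat.

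Of 76 sets of values checked, 6 held a rat far from the others of its group, where about 1 in 20 sets would by chance. miR-96-5p was 6.22 CPM in TPN 16 and 11.6 to 14.1 CPM in the other TPN rats. miR-15b-5p was 56.3 CPM in Control 5 and 18.4 to 27.3 CPM in the other Controls. miR-144-5p was 3.38 CPM in TPN 6 and 1.05 to 1.32 CPM in the other TPN rats. miR-192-5p was 30609 CPM in Control 19 and 62305 to 77602 CPM in the other Controls. TPN 8 had 14788757 reads, the other TPN rats 7552545 to 8590107. The sixth is the predicted share of Control 12 given above.

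Among rows under the filter, 7 had reads in at least 2 TPN rats above the limit that 0 reads in Control allows, and 201 (2 of them rat-named) had such reads in Control only. Chosen after their values were seen, the 7 were miR-431 (16 reads in 4 TPN rats), novel_miR_386 (11 in 4), novel_miR_139 (8 in 3), novel_miR_511 (8 in 2), miR-20a-3p (7 in 4), miR-369-3p (5 in 3) and miR-879-5p (5 in 3).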

How the results depend on the processing

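TMM scaling, the plain edgeR test, leaving out Control 5, 12 and 19, the rat number as a covariate, library quality weights, and list tests against rat-named rows or with TMM were chosen after seeing the data, as were the values set against the median, the alternatives for single lists and miR-431; the others were planned. No paired analysis was possible because the groups share only 1 rat number. In no case below was the cause tested unless stated.

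The counts of rows past an adjusted p of 0.05 stayed at 0 under each alternative except DESeq2 (3 higher, 109 lower) and library quality weights (2 lower, miR-451-5p and, chosen after its value was seen, miR-190b-5p); the nearest miss was miR-451-5p with the rat number as a covariate (adjusted p = 0.051). The median log2 fold change of rat-named rows was -0.26, against 0.05 with RLE, 0.10 with TMM, 0.20 with TMM without miR-148a-3p and 0.91 with upper-quartile scaling, whose factors reached 6.24 in Control 12. The named values were also set against the median rat-named row of the same scaling. A scaling factor moves all rows of a library nearly alike, so agreement on this measure was largely fixed in advance and does not show robustness to scaling. Of 34 named microRNAs, 30 stayed on the same side under all 4 other scalings, except that miR-148a-3p had no value with TMM without miR-148a-3p. The 4 that did not (with upper-quartile scaling) lay within 0.057 of that median. Without that median, 7 kept their sign under every alternative run, which mostly reflects the shift of the whole table; over all of them, 520 of the values at other settings kept direction and side of the threshold, 5 passed the threshold and 49 reversed, and leaving out single libraries reversed 11 and left 363. Upper-quartile scaling turned the sign of these log2 fold changes, with the rat-named median at 0.91: miR-96-5p 0.12, miR-505-3p 0.31, miR-7a-5p 0.70, miR-203a-3p 0.55, miR-15b-5p 0.30, miR-200c-3p 0.41, miR-144-5p 0.018, miR-143-5p 0.59, miR-26b-5p 0.69, miR-194-5p 0.88, miR-16-5p 0.48, miR-183-5p 0.43, miR-214-3p 0.41, miR-210-3p 0.55, miR-150-5p 0.75, miR-122-3p 0.91, miR-182 0.41, miR-342-3p 0.57, miR-146a-5p 0.91, miR-148b-3p 0.91, miR-143-3p 0.97, miR-34a-5p 0.62, miR-101b-3p 0.91, miR-192-5p 1.29, miR-122-5p 1.37. TMM without miR-148a-3p reversed miR-122-3p 0.018, miR-146a-5p 0.013, miR-148b-3p 0.010, miR-143-3p 0.067, miR-101b-3p 0.0092, miR-192-5p 0.39 and miR-122-5p 0.47. For miR-192-5p and miR-122-5p the values were 0.24 and 0.32 with RLE, 0.22 and 0.12 with DESeq2, 0.29 and 0.36 with limma-voom, 0.24 and 0.11 with edgeR (robust or not) and 0.30 and 0.38 with TMM; miR-122-5p was 0.086 with the rat number as a covariate. Without Control 5, 12 and 19, miR-101b-3p was 0.11, miR-200b-3p -0.23 and miR-21-5p -0.095; library quality weights gave miR-200b-3p -0.20. Leaving out each library in turn gave -0.0052 (without TPN 8) to 0.43 for miR-200b-3p, -0.30 to 0.0074 (without TPN 6) for miR-192-5p, -0.10 (without Control 16) to 0.34 for miR-21-5p and -0.48 (without Control 19) to 0.47 (without TPN 6) for miR-122-5p.

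The 2 higher lists became 0 with an estimated correlation, fry, a mean of at least 10 CPM, the more abundant arm only, rat-named rows only or without Control 5, 12 and 19 (then 2 lower), 10 with RLE or TMM, and 0 (without Control 12 or TPN 8) to 4 (without Control 7 or TPN 16) when single libraries were left out. For the miR-200 family with miR-141 and miR-429 the adjusted p ranged from 0.000166 (without TPN 16) to 0.195 (without TPN 8), and without Control 5, 12 and 19 its direction turned (0.997); for the miR-148 and miR-152 family it ranged from 0.00111 (without Control 5) to 0.195 (without TPN 8). Over the list alone, the 3 red blood cell members past the threshold stayed 3 in every leave-one-out fit and without Control 5, 12 and 19, and became 1 with a mean of at least 10 CPM (fewer members tested), RLE, TMM, TMM without miR-148a-3p or DESeq2, and 0 with upper-quartile scaling or edgeR (robust or not). The 2 members of the miR-183, miR-96 and miR-182 cluster became 1 with a pseudocount of 5, no filter, DESeq2, limma-voom or without Control 5, 12 and 19, 0 with RLE, upper-quartile, TMM, TMM without miR-148a-3p or edgeR (robust or not), and 1 (without Control 5, 7, 18 or 19 or TPN 11, 15 or 16) to 3 (without Control 12 or TPN 6). The difference in the top-10 share kept its direction and side in every alternative run (1.19 percentage points among rat-named rows to 1.75 without Control 18). Since the groups did not overlap with all rats, leaving out libraries could not have changed this, so those runs do not show robustness. Only the other row sets could have. That of miR-148a-3p became 16.4 points without Control 5, 12 and 19 and passed, while miR-122-5p had a log2 fold change of -0.89 there. The difference in totals ranged from 2603824 (without TPN 8) to 4813667 reads (without Control 7, exact permutation p = 0.0159) over single libraries and was 987711 without Control 5, 12 and 19 (exact permutation p = 0.768). The miR-431 difference, 0.369 CPM, ranged from 0.196 (without TPN 16) to 0.461 (without TPN 15) when single libraries were left out. Leaving out Controls cannot move it, since all have 0 reads. Without Control 5, 12 and 19 it was again 0.369, with an exact permutation p of 0.196. Ties among the rats with 0 reads keep that test from passing with so few rats. Depth limits rare rows most: 1 read is 0.712 CPM in Control 12 and 0.0676 CPM in TPN 8.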

Other observations

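The tests of miR-122 by rat number were chosen only after its levels were seen; those of the Dlk1-Dio3 cluster and of red cell microRNAs were fixed before their own results were seen, but after the TPN against Control comparison was seen.

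The 2 arms of the miR-122 hairpin moved apart between rats. miR-122-5p, the functional arm, held 2.54% to 6.75% of the reads in the 4 rats numbered below 10 (Control 5 and 7, TPN 6 and 8) and 12.6% to 33.5% in the others except Control 19 (2.18%), in both groups. With the group in the model its log2 difference was -1.75 (95% interval -3.22 to -0.28), though an exact permutation test without the group gave p = 0.0515, and that of miR-122-3p was 0.66 (0.30 to 1.01), so a lower level of the whole hairpin is argued against. The ratio of the arms ran from 63.3 to 139 in rats numbered below 10 and from 69.4 to 1079 in the other 7 (log2 difference -2.36, exact permutation p = 0.0273, 0.0409 after adjustment over the 3 tests made). That adjustment does not cover the choice of miR-122 and of the cut at 10 after the data were seen. Over all 535 rows, 1 passed an adjusted p of 0.05 between these numbers, miR-374-5p (1.33, adjusted p = 0.0108, chosen after its value was seen). Neither arm of miR-122 passed there (limma-trend adjusted p = 0.293 for miR-122-5p and 0.141 for miR-122-3p). The labels do not say what the numbers stand for, and the 2 number ranges hold both groups.

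A rise of the whole Dlk1-Dio3 cluster, the imprinted region that holds miR-431 (of 41 list members in the table, 38 lie among the 59 microRNA genes between Dlk1 and Dio3 in assembly GRCr8), was tested as a possible explanation of the miR-431 reads in TPN. The other 58 rows of the list, each 1 mature sequence, summed to 60.9 CPM ± 29.0 (n = 5) in TPN and 63.9 CPM ± 31.5 (n = 6) in Control (exact permutation p = 0.868), a difference of -3.04. The sum rests largely on miR-379-5p and miR-127-3p (means of 22.5 and 17.9 CPM), so it says little about members as rare as miR-431. The highest TPN rat had 109 CPM, under 2.16 times the Control mean. A rise of the summed level as large as that of miR-431 is therefore argued against. A smaller one stays open: the camera test of limma-trend placed the 7 tested rows of the list on the higher side of the other rows (adjusted p = 0.144, from a p of 0.0187), with a call without Control 7 (adjusted p = 0.0190) or TPN 15 (0.0363), and on the lower side without Control 5, 12 and 19 (0.364).

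If the content of red cells set miR-451-5p, other microRNAs known from red cells (miR-15b, miR-16, miR-96, miR-182, miR-183, miR-185 and miR-363, a list written before the test but after miR-96, miR-182, miR-183 and miR-15b had been seen to be lower in TPN) would follow it from rat to rat within groups. Their median correlation with it was 0.541, at the 85.65th percentile of 10000 random lists of like abundance (median 0.202). The rows ran from miR-16-5p at 0.869 to miR-185-5p at -0.080 and miR-363-3p at -0.699; these last 2 rows go the other way. The percentile does not reach the 95th percentile set beforehand, so it stays open. The list had 8 measured rows.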
